A study of Mus musculus with 2 samples.

How the data were processed

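The data are gene-level RNA sequencing values for 2 libraries of the mouse hair follicle stem cell line iHFSC2, 1 from cells that carry the empty lentiviral vector and 1 from cells that carry the circSmad5 hairpin. Per the labels' protocols, total RNA was extracted with Trizol and 3 µg went into each preparation. Ribosomal RNA was removed with a Ribo-Zero kit and the libraries were made with the NEBNext Ultra Directional kit, which keeps the strand of each transcript. HISAT2, HTSeq 0.13.5 and the builds GRCm38 and GRCh38 are listed in the submitters' processing notes, without a version for HISAT2 and without the role of either build. The aligner's settings, the annotation, the strand setting of the counting and the handling of reads that match several places are not given in the sources used here.

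The authors deposited a table of 22383 genes with a read count and an FPKM value per library, per the file headers. The deposited counts are whole numbers and were not normalized. The deposited FPKM values were checked against the counts. The gene length that each pair of values implies, with the column's own count total as the depth, was a whole number within 0.001 bases for 100.0% of genes above 0 in either library. It equalled the summed exon length of GENCODE M21 for 98.0% of these genes in the empty vector library and 98.1% in the shcircSmad5 library. The FPKM values therefore carry the same information as the counts divided by total and length. Each value column was matched to a library by its name, and 0 columns of values were left unmatched.

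Gene coordinates and biotypes came from GENCODE M21, on GRCm38, by gene ID. Of the gene IDs, 22319 were found there and 64 were not. The table holds 0 ribosomal RNA, 0 small nucleolar RNA and 0 microRNA genes, so these classes could not be read. Long noncoding RNA stands here for the biotypes lincRNA, antisense, processed transcript, bidirectional promoter and sense overlapping. TEC models are unspliced transcripts that await experimental testing. The hairpin's target sequence was matched to the exons of Smad5 in the same release.

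Counts were scaled by TMM in edgeR 4.0.16 with R 4.3.3, and ratios were taken as shcircSmad5 over empty vector. Intervals of a ratio are exact Clopper-Pearson 95% intervals of the split of a gene's counts between both libraries. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and the spread between cultures was not measured. With 1 library per group there was no test, no p-value and no standard error. A gene was called higher or lower by a size rule: at least 20 counts in 1 or both libraries, a ratio of at least 2-fold, and an interval that excludes 1. A count of 0 was set to a floor of 3 counts, and the ratio is then given as a bound.

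The size rule was tested on simulated counts for this comparison, drawn from the means and totals of these libraries. With counting error alone, the rule picked 50 of 50 genes simulated at 3.0-fold, 3 of 50 at 1.5-fold and 40 of 13120 unchanged genes, among 13320 genes. With an assumed biological coefficient of variation of 0.2, it picked 43 of 50 at 3.0-fold and 397 of 13142 unchanged genes, which is 3.02%, among 13340 genes.

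The size rule, 41 gene lists, the rule for named genes and most other settings were fixed before the data were examined. Named are protein-coding genes with at least 100 counts in 1 or both libraries that pass the size rule, without predicted or unnamed models. From these come the 10 highest and the 10 lowest ratios, the 5 largest rises and the 5 largest falls in CPM, the count scaled to a common library total. Smad5 is always named. From each list come up to 4 members that pass the size rule with the most counts, or up to 3 with the most counts where none passes. Of the list members that this rule names, 1 is not reported here. Genes outside the rule, and the breakdowns by biotype and by chromosome, were chosen after their values were seen. A list's median log2 ratio over members with at least 20 counts was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. That percentile describes these libraries and is not a p-value. The random lists were drawn from measured genes of every biotype, without matching on biotype. They can hold long noncoding RNA genes and TEC models, whose medians were 0.90 and 0.64, which can lower the percentile of a protein-coding list. Intervals of list medians and of other medians over genes come from 10000 bootstrap draws of the genes and describe the spread over genes.

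The other settings fixed beforehand were total counts, DESeq2 1.42.0 size factors, upper quartile scaling, and totals without the mitochondrial and structural genes and the top 20 genes. Further ones were the deposited FPKM as log2(FPKM + 0.1), a prior count of 2, other count minimums and fold limits, protein-coding genes alone, unmatched random lists, and means in place of medians. Centring each chromosome and using the autosomes alone were added after the data were seen. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9. No read of the circular RNA itself was analysed here, because the counts are per gene.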

Results

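RNA was sequenced from 2 stable derivatives of iHFSC2, an immortalized line of mouse hair follicle stem cells. The shcircSmad5 line expresses a short hairpin against circSmad5, a circular RNA made from the Smad5 gene, and the control line carries the empty lentiviral vector. Puromycin was added from day 4 after infection, and the lines were stable at day 15. Each group had 1 library, so none of the differences reported has a replicate check, and differences between separately selected lines cannot be set apart from effects of the hairpin. The total gene count was 39261010 in the empty vector library and 38382081 in the shcircSmad5 library. Of 22383 genes, 13596 had at least 20 counts in 1 or both libraries. Protein-coding genes took 99.2% of the counts in the empty vector library and 98.2% in the shcircSmad5 library.

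The comparison sets a line with a hairpin against circSmad5 beside a line with the empty vector. No line with a control hairpin was included, so effects of expressing any hairpin cannot be set apart from those of losing circSmad5. The hairpin's target, TCCAGCAGAGGACTTGCACTA, joins the end of an exon of Smad5 to the start of an exon that lies upstream of it, which is the layout of a back-splice junction. Its first 10 bases are the last bases of exon 4 (GRCm38 chromosome 13, 56728510 to 56728629, plus strand), and its last 11 bases are the first bases of exon 2 (56723429 to 56723996). The whole 21-base target occurs in none of the 3 linear Smad5 transcripts whose exons it matched. Smad5 (ENSMUSG00000021540, chromosome 13, 56703010 to 56742377), a transducer of BMP signals, had 3109 counts in the empty vector library and 3413 in the shcircSmad5 library. That is 80.9 and 87.0 CPM, a log2 ratio of 0.10 (95% counting interval 0.03 to 0.18). A gene count does not separate circular from linear RNA, so it gives no measure of the knockdown, and the level of circSmad5 was not measured by these values.

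By the size rule, 1146 genes were higher and 848 were lower in the shcircSmad5 library. Among protein-coding genes with at least 100 counts in 1 or both libraries, without unnamed models, those with the lowest ratios included the follicle keratin Krt17, the growth factor receptor Fgfr1 and the secreted bulge marker Dkk3. These 3 genes had 134, 15 and 3 counts left in the shcircSmad5 library. The highest ratios of this set included the interferon-induced gene Ifit1, the prohormone convertase Pcsk2 and the cyclophilin Ppia. The long noncoding RNAs stood apart as a class, with 288 of 630 higher and 43 lower. Among 11605 protein-coding genes the balance was the other way, with 535 higher and 740 lower.

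**Figure D1:**
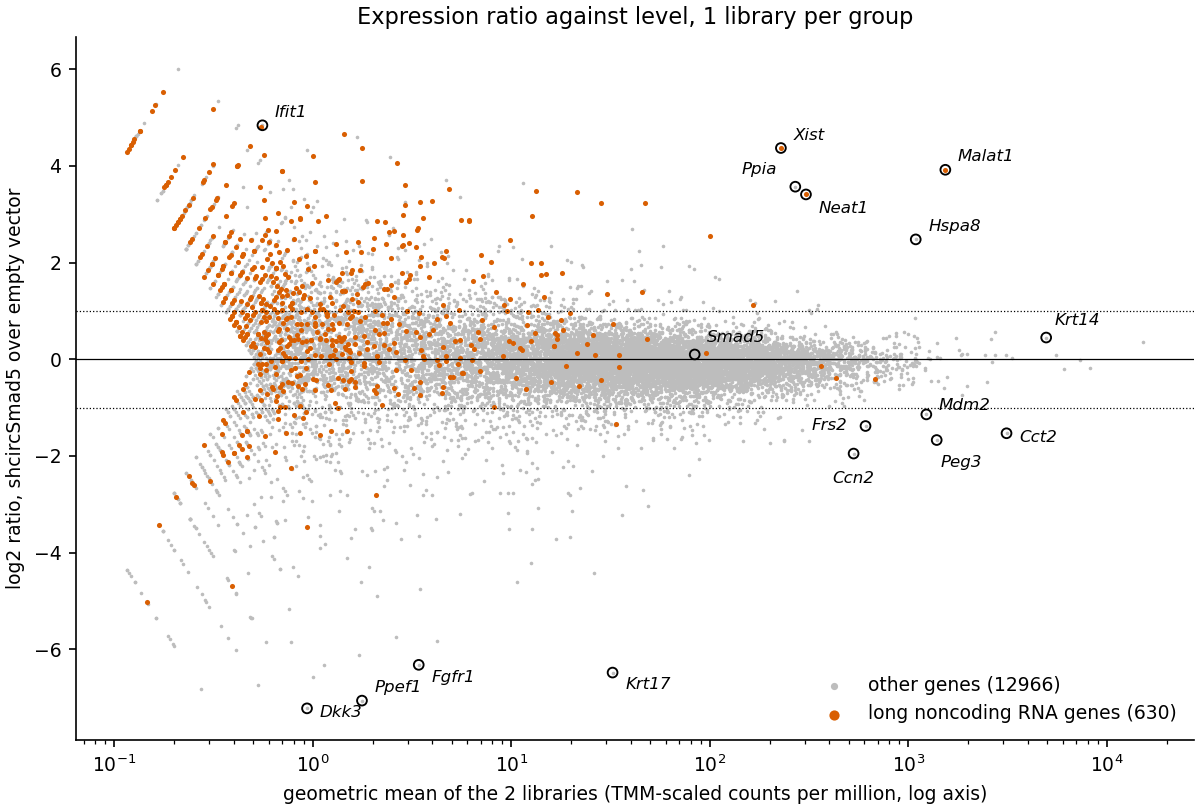
Log2 ratio of shcircSmad5 over empty vector for 13596 genes (vertical axis) against the geometric mean of both libraries in scaled CPM (horizontal log axis), with 0 counts drawn at the floor of 3. Orange points are the 630 long noncoding RNA genes, whose median is 0.90; dotted lines mark 2-fold, and circles mark genes discussed in the text, among them Krt17 at -6.48 and Malat1 at 3.92.

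Krt17 (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029) went from 11738 counts in the empty vector library to 134 in the shcircSmad5 library, 89.4-fold lower (95% counting interval 75.4 to 107). Fgfr1 (ENSMUSG00000031565, chromosome 8, 25513654 to 25575718) had 1173 and 15 counts and was 79.8-fold lower (48.2 to 143). Dkk3, a secreted member of the Dickkopf family, had 439 and 3 counts and was 149-fold lower (50.8 to 727). The phosphatase gene Ppef1 had 785 and 6 counts (134-fold lower), and Pir had 376 and 4 (96.0-fold lower), both on the X chromosome. The other genes among the 10 lowest of the set were Serpina9 (113-fold lower), the synaptic scaffold gene Homer2 (107-fold), Setbp1 (392 and 5 counts), the sodium pump modulator Fxyd2 (69.6-fold) and the keratinocyte cytochrome P450 gene Cyp2b19 (64.8-fold). Several of these had 1 to 8 counts left in the shcircSmad5 library, and the intervals are correspondingly wide, as for Serpina9 with 1 count (19.9 to 4516).

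Among the 10 highest of the set, Ifit1 had 4 counts in the empty vector library and 117 in the shcircSmad5 library, 28.6-fold higher (10.9 to 107). Pcsk2 was 24.3-fold higher, the kinase gene Rps6ka6 20.1-fold, the adhesion molecule gene Alcam 13.1-fold, and the iron-carrier binding protein gene Lcn2 11.5-fold. The potassium channel gene Kcnj15 had 50 and 663 counts, a log2 ratio of 3.70. The sphingolipid enzyme gene Sptlc3 was 10.2-fold higher and Enpp5 9.88-fold. H3c13, a replication-dependent histone gene, was 12.5-fold higher. All of its exonic bases lie under a gene on the opposite strand, so its value is uncertain where counting ignored strand. Ppia (ENSMUSG00000071866, chromosome 11, 6415443 to 6419817) went from 3004 to 36432 counts, 11.9-fold higher (11.4 to 12.3). Ppia and the heat shock cognate gene Hspa8 have many near-identical pseudogenes, and their values are uncertain where reads were shared among copies.

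Among the genes of this set that passed the size rule, the largest gains in level were in Hspa8 (462 CPM in the empty vector library and 2571 in the shcircSmad5 library), Ppia (78.2 and 929), the platelet chemokine gene Ppbp (169 and 449), the secreted protease gene Htra1 (236 and 516) and the ubiquitin-conjugating enzyme gene Ube2h (242 and 499.6). The largest losses among them were in the chaperonin subunit gene Cct2 (5310.4 and 1839 CPM), the imprinted gene Peg3 (2476 and 780.4), the p53 ligase gene Mdm2 (1829.8 and 830.2), the matricellular gene Ccn2 (1041 and 269.9) and the fibroblast growth factor receptor adaptor gene Frs2 (979.8 and 378). Cct2, Frs2 and Mdm2 lie within 1 Mb of each other on chromosome 10, from 117051001 to 117710758.

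As a list, markers of hair follicle stem cells lay low among matched random lists, while most basal keratinocyte and differentiation genes differed little. Of 22 measured stem cell and bulge markers, 4 were lower and 1 was higher. Dkk3, the Wnt antagonist gene Sfrp1 (10.2-fold), the bulge keratin gene Krt15 (3.27-fold) and the activin antagonist gene Fst (2.49-fold) were lower. Angptl7 was 64.6-fold higher (11.2 to 2591) on 1 count in the empty vector library and 66 in the shcircSmad5 library. The list's median log2 ratio was -0.46, with a bootstrap interval of -0.76 to 0.01, and 1 of 10000 matched random lists lay below it. With each chromosome centred at its own median, an alternative added after the data were seen, the list's median was -0.29. Sox9, a regulator of these cells that did not pass the size rule, had a log2 ratio of -0.77 (-0.82 to -0.72).

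The 24 basal keratinocyte markers had a median of 0.05, at percentile 92.8, and Krt17 was the only member past the size rule. Krt5, Krt14 and Col17a1, which mark the basal layer, had log2 ratios of 0.09, 0.45 and 0.09. The 27 epidermal differentiation genes had a median of 0.07, at percentile 83.1, with 1 higher and 5 lower. Zfp750, a transcription factor of terminal differentiation, was 4.76-fold higher. The cornified envelope genes Sprr2a1 (5.74-fold), Sprr1a (2.68-fold) and Lce1f (2.54-fold), with Krtdap (3.19-fold) and the desmosomal cadherin gene Dsg1a (2.49-fold), were lower. Of 9 hair shaft and inner root sheath genes (median -0.22, percentile 13.7), Prdm1 (2.28-fold) and Krt32 (2.00-fold) were higher, and Krt75 was 15.3-fold lower on 30 and 2 counts. Among 15 sebaceous and lipid genes (median -0.09, percentile 29.9), the desaturase gene Scd1 was 3.13-fold lower, and Fabp4 was at least 6.53-fold higher against the floor of 3 counts, with 0 and 20 counts and a lower counting limit of 4.84-fold. The 23 cholesterol synthesis genes had a median of -0.29, at percentile 1.28, with Acat2 on chromosome 17 the only member past the rule (2.05-fold lower). That median was -0.18 with each chromosome centred.

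**Figure D2:**
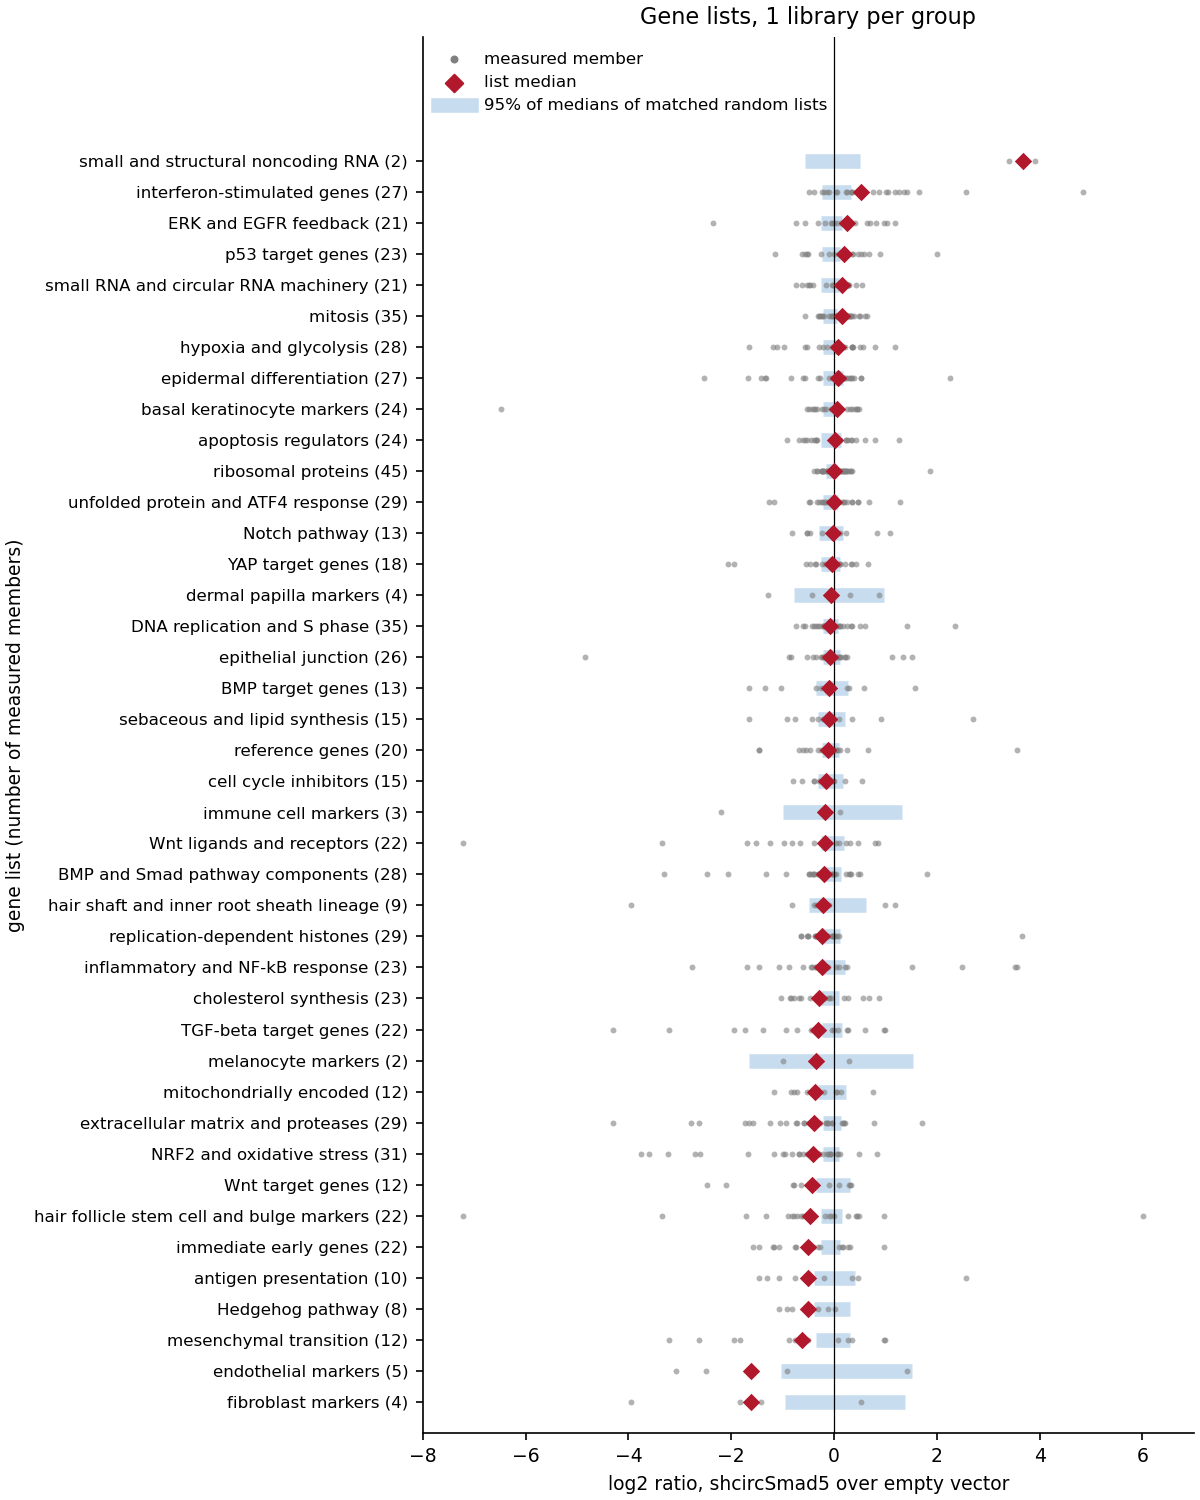
Log2 ratio of shcircSmad5 over empty vector (horizontal axis) for the measured members of 41 gene lists (grey points), with each list's median (red diamonds) and the range of 95% of the medians of 10000 matched random lists (blue bars). The medians run from -1.62 for 4 fibroblast markers to 3.67 for the structural noncoding RNAs, of which 2 were measured.

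Smad5 belongs to the BMP pathway. The medians of the BMP and Smad component list and of the BMP target list lay within the central 95% of matched random lists. Those of TGF-beta and Wnt targets lay below it. The component list is not specific to BMP, as it also holds TGF-beta ligands and receptors. With each chromosome centred, the medians of the component list and of the TGF-beta targets were both -0.13. Of 28 BMP and Smad components (median -0.20, percentile 4.37), 4 were lower and 1 was higher. The ligand genes Bmp4 (5.57-fold, 60 and 11 counts) and Tgfb2 (4.20-fold, 37 and 9 counts), and the antagonist genes Chrd (9.87-fold, 29 and 3 counts) and Fst, were lower. Bmp8a was 3.51-fold higher. Smad1, a close relative of Smad5, had a log2 ratio of -0.93 (-1.03 to -0.84) and did not pass the rule. The 13 BMP target genes had a median of -0.09, above that of 3596 of 10000 matched lists. Atoh8 was 3.00-fold higher, and Vegfa (3.16-fold), Runx2 (2.56-fold) and Gata6 (2.04-fold) were lower. Vegfa and Runx2 lie on chromosome 17, whose genes were lower as a whole in the shcircSmad5 library (median -0.42).

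Of 22 TGF-beta target genes (median -0.32, percentile 0.370), 5 were lower and 1 was higher. The collagen cross-linking enzyme gene Lox (19.7-fold), the fibronectin gene Fn1 (9.22-fold), Ccn2 (3.86-fold), the protease inhibitor gene Timp1 (3.33-fold) and Tgfbi (2.61-fold) were lower, and the smooth muscle actin gene Acta2 was 2.00-fold higher. This list's median was -0.13 with each chromosome centred. Of 12 Wnt target genes (median -0.42, percentile 0.710), Apcdd1 (4.32-fold) and Bmp4 were lower. The bootstrap interval of this median was -0.78 to 0.20, and with a minimum of 100 counts the median was -0.25. Of 22 Wnt ligand, receptor and antagonist genes (median -0.18, percentile 8.93), Dkk3, Sfrp1, Fzd1 (3.26-fold), Fzd7 (2.85-fold) and Wnt3a (2.36-fold) were lower and none was higher, and the median was -0.28 with each chromosome centred. The 8 Hedgehog pathway genes had a median of -0.50, at percentile 0.580, with Gli2 2.10-fold lower, and one of -0.29 with each chromosome centred. The 13 Notch pathway genes had a median of -0.02, at percentile 61.8, which turned positive under 3 of the other scalings. Nrarp, a Notch feedback gene, was 2.12-fold higher. The 18 YAP target genes had a median of -0.04, at percentile 57.4, which also turned positive under 3 other scalings, with Ccn2 and Tgfb2 lower.

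Proliferation genes were near level between the libraries. None of 35 mitosis genes passed the size rule. Their median of 0.16 lay above that of 9996 of 10000 matched random lists, but at percentile 95.9 of unmatched ones, and their most abundant members Mki67, Tpx2 and Top2a had log2 ratios of 0.04, -0.32 and 0.31. Among 35 replication genes (median -0.08, percentile 43.1), Fen1 (5.11-fold) and E2f2 (2.69-fold) were higher, and most of the exonic bases of Fen1 lie under exons on the opposite strand. The 23 p53 target genes had a median of 0.19, at percentile 99.9 of matched lists and 95.7 of unmatched ones. The noncoding gene Pvt1 was 3.99-fold higher, in the direction of the long noncoding RNAs as a class, and Mdm2 was 2.20-fold lower. None of 15 cell cycle inhibitor genes passed the rule (median -0.16, percentile 20.1), and Trp53, Cdkn1b and Cdkn1a had log2 ratios of -0.16, -0.11 and -0.09. Of 24 apoptosis regulators (median 0.02, percentile 74.4), Casp4 was 2.41-fold higher.

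The list of interferon-stimulated genes had a median above 0, and the immediate early list and the NRF2 and oxidative stress list had medians below 0. Of 27 interferon-stimulated genes, 9 were higher and none was lower, with a median of 0.53 at percentile 99.9, which was 0.35 with no count minimum. Besides Ifit1, they included the RNA sensor gene Ifih1 (2.70-fold), Xaf1 (2.40-fold) and Gbp7 (2.26-fold). Their levels were low, with a median over members of 4.58 CPM in the empty vector library and 8.01 in the shcircSmad5 library. The 10 antigen presentation genes had a median of -0.50, at percentile 0.760. B2m (2.72-fold), H2-D1 (2.49-fold) and H2-K1 (2.09-fold) were lower, and the immunoproteasome gene Psmb9 was 5.88-fold higher on 5 and 30 counts. H2-D1, H2-K1 and Psmb9 lie on chromosome 17, and the list's median was -0.09 with each chromosome centred.

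Of 23 inflammatory genes (median -0.24, percentile 2.90), 4 were higher and 4 lower. The mean over members was 0.03, and the median with a minimum of 100 counts -0.36, so the list has no clear direction. The interleukin receptor antagonist gene Il1rn (6.80-fold), the cyclooxygenase gene Ptgs2 (3.23-fold), Il1a (2.74-fold) and Ccl7 (2.10-fold) were lower. Lcn2, Csf3 (11.8-fold), Ccl20 (5.63-fold) and Il18 (2.87-fold) were higher, each on 2 to 15 counts in the empty vector library. Of 22 immediate early genes, 5 were lower and none was higher, and their median of -0.50 lay below that of all 10000 matched lists. The phosphatase gene Dusp1 (2.97-fold) and Ier3 (2.75-fold), both on chromosome 17, and the transcription factor genes Jund (2.28-fold), Atf3 (2.24-fold) and Jun (2.09-fold) were lower. The list's median was -0.41 with each chromosome centred. The 21 ERK and EGFR feedback genes had a median of 0.26, at percentile 99.9, with Tgfa (2.28-fold) and Dusp5 (2.06-fold) higher and Dusp4 5.10-fold lower.

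Of 31 NRF2 and oxidative stress genes, 7 were lower and none was higher, and their median of -0.40 lay below that of all 10000 matched lists. The glutathione transferase genes Gsta4 (3.21-fold) and Gsta1 (6.04-fold), the glutathione peroxidase gene Gpx2 (6.51-fold) and the aldehyde dehydrogenase gene Aldh3a1 (9.31-fold) were lower. Hmox1, a classical target of NRF2, had a log2 ratio of -0.96 (-1.04 to -0.88) and did not pass the rule. The 29 unfolded protein response genes had a median of -0.00, at percentile 75.6, which was above 0 under the other scalings. Sdf2l1 was 2.42-fold higher, and Vldlr (2.40-fold) and Atf3 were lower. Of 28 hypoxia and glycolysis genes (median 0.08, percentile 96.0), Bnip3 was 2.27-fold higher, and Vegfa, the hexokinase gene Hk1 (2.27-fold) and Adm (2.14-fold) were lower.

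The medians of the matrix and mesenchymal lists were below 0, while most of their members did not pass the size rule. Of 29 extracellular matrix and protease genes (median -0.38, percentile 0.0300), 8 were lower and 1 was higher. The tenascin gene Tnc (6.14-fold), Timp3 (3.17-fold) and the plasminogen activator gene Plat (2.07-fold) were lower, with Lox and Timp1, and the protease inhibitor gene Serpinb2 was 3.28-fold higher. Of 12 mesenchymal transition genes (median -0.63, percentile 0.0300), Fn1, Tnc, Prrx1 (3.88-fold) and Twist2 (3.54-fold) were lower and Acta2 was higher. The bootstrap interval of the mesenchymal median was wide, -1.89 to 0.31, and with no count minimum the median was -0.17. Among 26 epithelial junction genes (median -0.08, percentile 32.7), the simple-epithelium keratin genes Krt8 (2.85-fold) and Krt7 (2.55-fold) and the junction gene Tjp3 (2.18-fold) were higher, and Marveld3 was 28.9-fold lower on 85 and 3 counts.

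Markers of other skin cell types were sparse in both libraries. Of 16 fibroblast markers 4 were measured (median -1.62, percentile 0.580), and Col6a3 (15.3-fold), Twist2 and the growth factor receptor gene Pdgfra (2.65-fold) were lower, with at most 161 counts. The fibroblast median was -0.45 with a minimum of 100 counts and -0.81 on FPKM. Of 13 endothelial markers 5 were measured (median -1.61, percentile 0.660). Kdr (8.42-fold), Vwf (5.62-fold) and Pecam1 (3.06-fold) were lower, and Egfl7 was 2.69-fold higher, with at most 81 counts. With that minimum only 1 endothelial marker was left, at -0.91, and the median of the 5 was -0.79 on FPKM. The 4 measured dermal papilla markers had a median of -0.05, at percentile 33.8, which turned positive under 3 other scalings and was 0.60 with a minimum of 100 counts. Fgf7 was 2.45-fold lower. Among 3 immune cell markers (median -0.18, percentile 28.3), Csf1r was 4.59-fold lower on 36 and 8 counts. The immune median was -0.73 with no count minimum, and the mean was -0.76. The 2 measured melanocyte markers, Mitf and Pmel, had log2 ratios of -0.99 and 0.29 (median -0.35, percentile 22.6).

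Long noncoding RNAs were the class with the largest shift. Their median log2 ratio was 0.90, against -0.05 for protein-coding genes. Of the structural noncoding RNA list only the nuclear RNAs Malat1 and Neat1 were measured. Malat1 had 15187 counts in the empty vector library and 234509 in the shcircSmad5 library (15.1-fold higher), and Neat1 had 3592 and 39017 (10.6-fold higher). The list's median of 3.67 lay above that of 9999 of 10000 matched random lists. Of 228 lincRNA genes 83 were higher and 21 lower, of 196 antisense genes 93 were higher and 12 lower, and of 157 processed transcripts 87 were higher and 4 lower. TEC models, with 201 of 667 higher and 24 lower, moved the same way. Of all 1146 higher genes, 529 were noncoding RNA, TEC or sense intronic models.

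Genes that every cell uses differed little as groups, with exceptions. The 45 ribosomal protein genes had a median of 0.01, at percentile 88.2, and only Rps18 passed the rule (3.65-fold higher). Ribosomal protein genes such as Rps18 have near-identical pseudogenes, and its value is uncertain where reads were shared among copies. The 20 reference genes had a median of -0.12, at percentile 24.7, with Ppia higher and B2m and the glucuronidase gene Gusb (2.75-fold) lower, while Actb, Gapdh and Rplp0 had log2 ratios of -0.21, 0.08 and -0.06. The 12 mitochondrially encoded genes had a median of -0.36, at percentile 1.10, with mt-Nd3 2.25-fold lower on 22 and 10 counts. The 29 replication-dependent histone genes had a median of -0.23, at percentile 2.23, and only H3c13 passed the rule. The histone median was -0.01 with each chromosome centred. None of 21 genes for small RNA and circular RNA processing passed the rule. Their median of 0.16 lay at percentile 99.7 of matched lists and 91.4 of unmatched ones and was 0.09 with each chromosome centred, their mean was -0.02, and Ago2, Hnrnpl and Dhx9 had log2 ratios of 0.16, 0.18 and 0.05.

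Genes of particular chromosomes were shifted together. Among protein-coding genes with at least 100 counts, the median log2 ratio was -0.47 for 299 genes on the X chromosome and -0.42 for 499 genes on chromosome 17, against -0.05 over the autosomes. On chromosome 17, 87.0% of the genes lay below 0, and on the X chromosome 88.0%. By the size rule, 40 X-linked genes were lower and 7 higher. The X-linked noncoding gene Xist, which coats and silences an X chromosome, had 1925 counts in the empty vector library and 40698 in the shcircSmad5 library, 20.7-fold higher, in the direction of the long noncoding RNAs as a class. On chromosome 13, which carries Smad5, the shift differed along its length. The median was -0.33 (bootstrap interval -0.40 to -0.25) for 105 genes in the first 30 Mb and -0.72 (-0.79 to -0.62) for 104 genes from 80 Mb on. For the 208 genes from 30 to 80 Mb, where Smad5 lies, it was -0.06 (-0.11 to 0.02). Smaller shifts were seen on chromosome 4 (median -0.24, 74.6% of genes below 0), chromosome 2 (-0.20, 72.4%), chromosome 8 (-0.17, 73.0%) and chromosome 5 (median -0.22). Chromosome 15 had the highest median, 0.17.

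**Figure D3:**
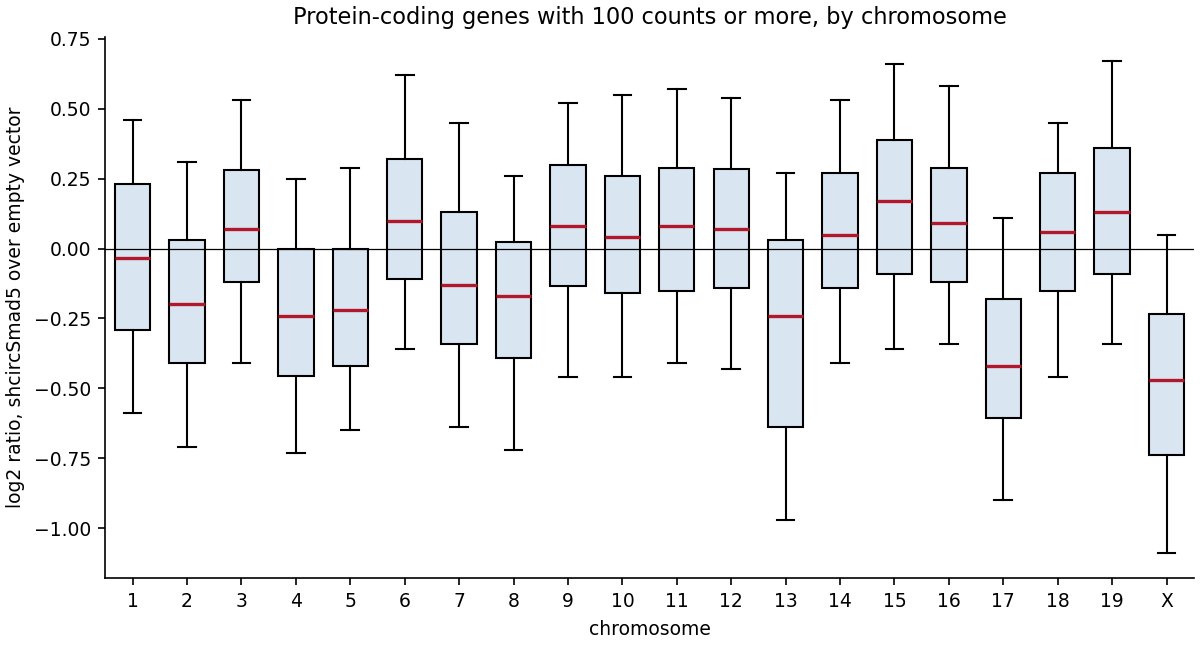
Log2 ratio of shcircSmad5 over empty vector (vertical axis) for protein-coding genes with at least 100 counts, by chromosome (horizontal axis). Red lines are medians, boxes span the quartiles and whiskers run from the 10th to the 90th percentile of genes; the boxes of chromosomes 17 and X, with medians of -0.42 and -0.47, lie below 0.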

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

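The chromosome-centred and autosome-only alternatives were chosen after seeing the data; the others were planned. No paired analysis was possible because each group has 1 library. With 1 library per group the number of higher and lower genes depends on the limits set. It was 439 and 463 with a minimum of 100 counts and 1672 and 1244 with no minimum, 1892 and 1753 at 1.5-fold, 379 and 292 at 4-fold, and 535 and 740 for protein-coding genes alone, where fewer genes were tested or the limit was moved. The other scalings gave 1159 to 1263 higher and 754 to 837 lower genes, and shifted each log2 ratio by at most 0.08. Of the 848 lower genes 754 to 837 kept their call under them; higher calls could not be lost, since these scalings raise every ratio. Centring each chromosome gave 1252 and 732, of which 1089 and 696 were the same genes, and the autosomes alone gave 1117 and 790. The log2 ratio of Smad5 was 0.12 to 0.17 under the other scalings and FPKM, 0.18 on totals without mitochondrial, structural and top genes, and 0.35 with its chromosome centred. That centring used the median of all of chromosome 13, -0.24, while the part from 30 to 80 Mb, where Smad5 lies, had a median of -0.06. The value of 0.35 therefore carries the shift of the chromosome's ends. No list median whose interval excluded 0 changed sign. On total counts, upper quartile, totals without those genes, and FPKM in turn, the median was 0.11, 0.11, 0.13 and 0.11 for basal keratinocyte markers, 0.08, 0.08, 0.09 and 0.08 for ribosomal proteins, and 0.22, 0.22, 0.24 and 0.22 for small RNA and circular RNA genes. With chromosomes centred, the ribosomal median was 0.10 and the histone median -0.01. Means in place of medians gave -0.27 for basal keratinocyte markers, which Krt17 pulls down, -0.81 for NRF2 genes, -0.73 for Wnt ligands and receptors, and -0.10 for histones. They turned the direction for epidermal differentiation (-0.18), hypoxia (-0.04), apoptosis (-0.02), small RNA and circular RNA (-0.02), replication (0.03) and inflammatory genes (0.03). The median of melanocyte markers was -0.99 with no minimum and with a minimum of 100 counts. Against unmatched random lists, mitosis lay at percentile 95.9, p53 targets at 95.7 and small RNA and circular RNA genes at 91.4. Apart from these by-construction changes the cause was not tested. Of 410 list medians under alternatives, 391 stayed within their interval and 19 moved; of 174 ratios of named genes 55 moved beyond their counting interval, none with a change of sign. FPKM with 0.1 added pulled low genes towards 0, such as Ifit1 to 3.17 and Dkk3 to -4.80. Homer2 went from -6.74 to -2.33 and Serpina9 from -6.82 to -3.02. Counting error limits the genes with few counts, and the spread between cultures is unknown.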

Other observations

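The genes and families in the next 2 paragraphs were chosen after their values were seen. All 3 measured pregnancy-specific glycoprotein genes were lower in the shcircSmad5 library, among them Psg28 (12.6-fold, 468 and 38 counts) and Psg18 (8.81-fold). Of 6 measured prolactin family genes 5 were lower, with Prl2c2 at 4225 and 464 counts (9.30-fold) and Prl8a9 at 1104 and 125 (9.02-fold), while Prl8a6 differed little (34 and 31 counts, log2 ratio -0.16). Members of both families resemble each other closely, so reads can be split among copies, and the prolactin genes lie on chromosome 13, where the log2 ratio of Prl2c2 (-3.22) was far below the median of -0.33 of the first 30 Mb. Of 18 protein-coding serpin genes 7 were lower and 1 was higher, including Serpina3b (22.5-fold lower). The protein-coding glutathione transferases went both ways, with 6 of 14 lower and 4 higher: Gstm1 was 13.4-fold lower, while Gstk1 was 11.1-fold and Gstm2 7.74-fold higher.

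Among the 10308 protein-coding genes with at least 100 counts, the largest losses outnumbered the largest gains: 32 were at least 16-fold lower and 4 at least 16-fold higher, and at 32-fold the numbers were 19 and 0. These numbers use the ratio alone, and at 4-fold they were 114 lower and 47 higher. Over genes of all biotypes with at least 20 counts, the size rule at 4-fold gave the other balance, with 379 higher and 292 lower. Among the keratins, Krt17 was 89.4-fold lower, with 134 counts left in the shcircSmad5 library. Other genes of the same chromosome 11 cluster differed among themselves: Krt15 (log2 ratio -1.71) and Krt13 (-1.20) were lower, while Krt14 and Krt16 were at 0.45 and -0.16. Of 13 noncoding host genes of small nucleolar RNAs, 5 were higher and 1 was lower, while 45.7% of all long noncoding RNA genes were higher. Gas5 had 154 and 1749 counts (11.1-fold higher), Snhg20 11 and 282 (25.1-fold), and Snhg5 241 and 986 (4.01-fold); Dancr, outside these 13, had 32 and 399 (12.2-fold). Other noncoding genes differed among themselves: Tug1 (5.86-fold), Oip5os1 (9.40-fold) and Snhg17 (2.62-fold, among the 13) were higher, while Kcnq1ot1, Zfas1, Firre and Airn had log2 ratios of 0.14, 0.09, 0.42 and -0.64. Of the 7 other chaperonin subunit genes none passed the size rule, and their median was -0.01 (bootstrap interval -0.38 to 0.00).

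In the 3 patterns that follow, the tests of GC content and of hairpin seed matches were set before their results were seen, and the others were chosen only after. The rise of long noncoding RNA genes is the first pattern. Strand-blind counting of only 1 library, acting through opposite-strand exons, cannot account for it as a whole. The 178 long noncoding genes (of 334 with at least 50 counts) that share no exonic base with the opposite strand had a median of 0.75 (0.48 to 0.95). For the 156 genes with such overlap a part is open, as they lay a further 0.52 higher (0.09 to 0.89). Overlap with introns of opposite-strand genes was not examined, so strand-blind counting of intronic reads stays open. Poly(A) selection of the empty vector library alone is argued against by histone mRNAs, which have no poly(A) tail and had a median of -0.23 (-0.29 to -0.12). A larger share of unspliced or nuclear RNA in the shcircSmad5 library is a candidate explanation, as 420 TEC and sense intronic models had a median of 0.70 (0.64 to 0.76). The rise of these models was seen beforehand as part of the same pattern, so it is no separate test. The rise was also uneven: by the size rule 288 of 630 long noncoding genes were higher, but not Kcnq1ot1 (0.14), Firre (0.42) or Airn (-0.64). Splicing and location in the cell were not measured for any of these genes. A biological effect of the hairpin and a counting difference unrelated to strand stay open too.

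The second pattern is the shift of chromosomes 17 and X; the other shifted chromosomes were not tested in this way. GC content and gene length do not account for it. After the trend of protein-coding genes was removed, chromosome 17 kept a median of -0.32 (-0.34 to -0.29) and chromosome X of -0.41 (-0.47 to -0.33). Without that correction, 1000 random sets of genes from the other autosomes, of the size of chromosome 17, gave medians from -0.09 to 0.03. These sets do not bear on GC content or length, and they treat genes as independent although other chromosomes shifted too. A few strong genes do not account for the shift either, as 85.2% of chromosome 17 genes and 85.3% of X-linked genes lay below the autosomal median. These shares describe the shift already seen in the medians and are no separate test. Over all chromosomes, each centred on its own mean, 138 pairs of adjacent 10-Mb bins correlated at 0.57, above the highest of 1000 shuffles (0.44). In this pooled value neighbouring bins tended to shift together, which copy number and other regional causes would both give. Chromosome 13, whose uneven shift was already seen, had bins from -0.76 to 0.12. The correlation was not computed without that chromosome, so 0.57 does not show such a pattern on chromosomes in general. Centring removes the shift of a whole chromosome, so this correlation does not bear on chromosomes 17 and X as wholes. Different gene copy number in the 2 stable lines was not tested, as DNA was not measured. It stays open with an effect of the hairpin and, for the X chromosome, silencing. Xist rose in the direction of the long noncoding RNAs as a class, but its log2 ratio of 4.37 lay above their upper quartile of 1.96. Whether its rise belongs to that class or to the X chromosome was not tested, so it decides nothing here.

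The third pattern is the joint fall of Cct2, Frs2 and Mdm2. By count these genes ranked 6, 68 and 21 in the empty vector library and 22, 409 and 95 in the shcircSmad5 library, so they stayed abundant. Between them, Cpsf6 ranked 1029, Yeats4 4329 and Cpm 8429 in the empty vector library. Cct2 had 5310.4 CPM there, against 199 (Cct3) to 490.5 (Cct6a) for the other chaperonin subunit genes. The 22 other p53 targets did not fall with Mdm2 as a group, with a median of 0.21 (0.00 to 0.37). That goes against lower p53 activity as the cause for Mdm2. The list's median with Mdm2, 0.19, had been seen beforehand, so this is no separate test, and p53 activity itself was not measured. An even copy change over the interval is argued against by 2 of the 3 other protein-coding genes with at least 100 counts between them, Yeats4 (-0.13) and Cpsf6 (0.46), whose counting intervals lay above -0.8. The other, Cpm next to Mdm2, had a log2 ratio of -0.82 (443 and 256 counts), so a change over parts of the interval stays open. A change in the copies of these 3 genes alone and a regulatory effect of the hairpin on each gene were not tested and stay open.

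Silencing through the seed of the hairpin's antisense strand was tested with the site TTGCACT in 3′ UTRs, as planned. The 1292 genes with a site, of 10177 with a 3′ UTR, differed in median log2 ratio from the rest by -0.00 (-0.03 to 0.02). This lay at percentile 12.6 among 4479 other sequences of the same length and GC content, and at 5.20 among the 1634 with a similar number of genes. The interval of the difference spans the lowest 5% of the other sequences (-0.02), so a small off-target effect could not be excluded or shown.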
